A study of Mus musculus and Homo sapiens with 28 samples.

How the data were processed

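Gene expression was measured by RNA sequencing in 28 libraries of 6 groups: 4 libraries of 786-O cells and 24 of Renca tumours. Groups were taken from the sample labels alone. Whether each mouse library is a separate animal and each human library a separate culture is not stated per library, so the p-values measure only the spread between these libraries. The submitters' processing notes name FastQC, TopHat, HTSeq and DESeq2 and the genome builds hg38 and GRCm38, without versions, order or annotation. The strandedness of the libraries and the way reads were assigned to overlapping genes are not given in the sources used here, so genes with overlapping or antisense neighbours (Igf2 among them) and families of similar genes (MHC, globin and histone genes) are uncertain in that respect.

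The human table was deposited by the authors as variance-stabilised values on the log2 scale, named so in the file header, with 1 row per gene symbol. The mouse table was deposited by the authors as regularised log values (rlog) on the log2 scale, made over the 24 mouse libraries together, with 1 row per Ensembl gene. Both are log2 values, so no further logarithm was taken. For the human table this departs from the analysis laid down before the data were examined, which foresaw a logarithm of the value plus 1 if the table did not hold counts. The comparisons, gene lists, thresholds and most alternatives were chosen before the data were examined. Alternatives chosen later are named as such.

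The human values fall on discrete steps with a common floor at 2.47, the value of a count of 0. Whole counts were recovered by fitting the transform to the 40 lowest steps. The fit left a root mean square residual of 2.9e-10 (log2), and 100% of values below 1000 counts were whole within 0.1. On simulated data 100% of the counts of 20000 genes were recovered. The recovered totals were 23956007 and 21447859 counts for the untreated and treated library of replicate 1 and 23492424 and 20834400 for those of replicate 2, with 22158, 24594, 22326 and 23297 genes above the floor. Between replicates the chi-square per degree of freedom over genes was 14.7 (untreated) and 14.9 (treated). The 2 libraries of a group are therefore not copies of one another. Over these genes together counting noise is a small part of the spread. Genes with many counts weigh most in this value, which does not speak for genes with few counts. Counts cannot be recovered from rlog values, and the mouse depth is unknown.

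Human genes were compared with limma 3.58.1 in R 4.3.3 (linear model of the 2 groups, empirical Bayes with a mean-variance trend). Of 56269 rows, 26916 held 1 value in all 4 libraries and 29353 were tested. The 2 experiments number the libraries in pairs, so pairing was checked: the correlation of the replicates' deviations between the groups was 0.158 over all 29353 genes and 0.511 over the 12731 genes with a mean of at least 5. The unpaired model is reported and the blocked model was run as an alternative.

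Mouse genes were compared with limma on the deposited rlog values, with 1 model of 4 group means over 24 libraries and the same empirical Bayes step. Of 46078 rows, 16906 were 0 throughout, and the 15916 with a mean rlog of at least 3 were tested. Gene names and coordinates come from GENCODE vM21 (GRCm38) through the Ensembl identifiers, which matched for 97.97% of all rows (935 did not) and 99.59% of those tested. The contrasts were SETD2 KD against WT without treatment, VE822 against untreated within each genotype label, SETD2 KD against WT under VE822, the interaction of the 2 factors, and SETD2 KD VE822 against WT untreated. All p-values were adjusted by Benjamini and Hochberg over the genes of a comparison, with a threshold of 0.05.

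Gene groups were tested with 34 lists: cGAS-STING, type I interferon, interferon-gamma and chemokines, MHC class I, MHC class II, T cell, cytotoxic and NK cell, checkpoint, B cell, macrophage, dendritic cell, neutrophil, fibroblast, endothelium, skeletal muscle, adipocyte, keratinocyte, red blood cell, renal epithelial identity, mitosis, replication, p53, ATR-CHK1, homologous recombination, NF-kB targets, hypoxia, mesenchymal transition, stress and unfolded protein response, cholesterol synthesis, histone, histone methylation around SETD2, mitochondrial transcripts, oxidative phosphorylation and ribosomal proteins. In mouse, the mean rlog over the members was taken per library and groups were compared by an exact two-sided permutation test of the difference in means, adjusted over the 34 lists. The smallest p this test can give was 0.000583 for 7 against 6 libraries, 0.00216 for 6 against 5 and 0.00126 for 7 against 5. The interaction of list means was tested with limma, and camera on the gene-wise fit was an alternative. In human, camera with its preset inter-gene correlation of 0.01 was used, with an estimated correlation, fry and the blocked model as alternatives. Members were also counted as risen or fallen past the threshold, adjusted over all genes and over the list alone.

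Genes named in the text come from a rule fixed before the data were examined. The targeted genes come first. They are followed by the 8 largest rises and 8 largest falls past the threshold that keep their direction under each left-out library, skipping predicted genes and receptor segments. For lists that pass, and for the cGAS-STING, type I interferon, MHC class I, T cell, mitosis and p53 lists in any case, up to 4 members with the smallest p are taken. Where fewer than 10 genes pass, the 10 with the smallest p are taken. The text names a part of what this rule gives, and that part was chosen after the values were seen. Some genes the rule gives are not reported here.

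Chromosomes were tested after the data were seen, over 9797 genes with a mean rlog of at least 8. For each library the median deviation of a chromosome's genes from their means over all libraries was taken, and groups were compared by the same permutation test over 20 chromosomes. The alternatives tried were other filters, trend and prior settings, centring and quantile normalisation, library weights, only the groups compared, and leaving out each library in turn. Chosen after the data were seen were voom on recovered counts (genes with a total of at least 10), a mean human value of at least 5, 4 list means as covariates, removal of chromosome medians, leaving out chromosomes 6, 8 and 10, and leaving out 5 doubted libraries. The doubted libraries are 4 with a skeletal muscle list mean above 6 (WT VE822 replicates 1, 2 and 4 and WT untreated replicate 4) and SETD2 KD VE822 replicate 4. Of the settings tried, the one that moved the median change of all mouse genes most was quantile normalisation, by -0.03 (log2) for VE822 in WT labels. The models were tested on simulated data with 100 changed genes. Simulated mouse libraries shared 1 spread per gene, pooled over the 4 groups. For some values the spread was wider in VE822 labels. The T cell list mean had an SD of 0.42 (WT) and 0.30 (SETD2 KD), against 0.18 and 0.09 untreated. Where that holds for a gene, recovery may be too high for comparisons with VE822 labels and too low between untreated labels. In mouse, changes of 0.5 and 1 (log2) were recovered in 83% and 96% of cases for VE822 in WT labels, 76% and 95% for VE822 in SETD2 KD labels, and 72% and 94% between genotype labels under VE822. Other software was data.table (1.17.8), statmod 1.5.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. No library was left out of the comparisons reported.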

Results

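RNA was sequenced from 2 systems, a human renal carcinoma cell line and mouse renal tumours. 786-O, an established human clear cell renal carcinoma line, was left untreated (n = 2) or given an inhibitor of CHK1, the kinase that ATR activates under replication stress, at 25 nM for 48 h (n = 2), in 2 separate experiments. The sample labels and the design text call this compound LY2606368, whereas the treatment protocol calls it LY2603618, and the sources used here do not settle which was given. Renca, a mouse renal carcinoma line, was grown as subcutaneous tumours labelled wild type (WT) or SETD2 knockdown (SETD2 KD). SETD2 is a histone methyltransferase that acts on transcribed gene bodies. The mice were untreated or received VE822, an ATR inhibitor, at 60 mg/kg by oral gavage on 5 days per week. The mouse groups held 7 libraries labelled WT untreated, 6 labelled WT VE822, 6 labelled SETD2 KD untreated and 5 labelled SETD2 KD VE822. The human libraries held 23956007 and 23492424 counts untreated and 21447859 and 20834400 counts treated, as recovered from the variance-stabilised values. The mouse values are regularised log2 values (rlog), so the depth of those libraries is unknown and no counting interval can be given. The median rlog value per mouse library ran from 9.13 to 9.21, and 12906 to 13381 genes per library lay above an rlog of 5.

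Setd2, the targeted gene of the mouse experiment, was at the same level in untreated tumours of both genotype labels and lower in every tumour labelled VE822. Setd2 (ENSMUSG00000044791, GRCm38 chromosome 9, 110532597 to 110618633, plus strand) had a mean rlog of 10.83 ± 0.07 (SD, n = 7) in libraries labelled WT untreated and 10.81 ± 0.07 (SD, n = 6) in libraries labelled SETD2 KD untreated. It was 10.03 ± 0.29 (SD, n = 6) in libraries labelled WT VE822 and 9.72 ± 0.21 (SD, n = 5) in libraries labelled SETD2 KD VE822. The 11 libraries labelled VE822 ran from 9.42 to 10.28 and the 13 labelled untreated from 10.70 to 10.91. Setd2 therefore goes against the genotype labels in the untreated tumours, and every direction given below for the mouse data is a direction between libraries as labelled.

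**Figure D1:**
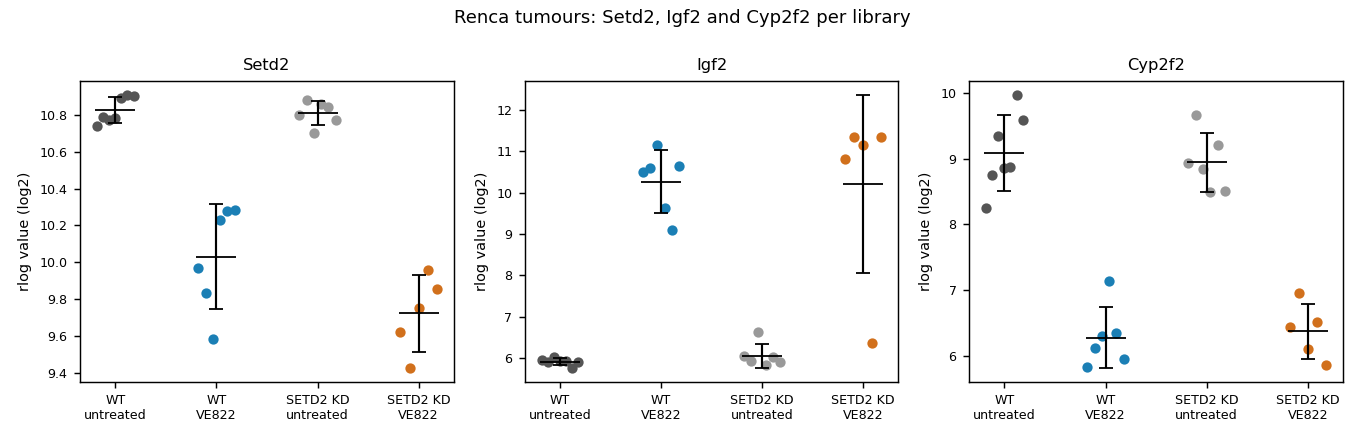
Rlog values (log2) of Setd2, Igf2 and Cyp2f2 in each mouse library, grouped by label; points are libraries, the horizontal line is the group mean and the bars are 1 SD. Setd2 lay between 9.42 and 10.28 in the libraries labelled VE822 and between 10.70 and 10.91 in those labelled untreated, and 1 library labelled SETD2 KD VE822 (replicate 4) had Igf2 at 6.37.

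The comparison of libraries labelled SETD2 KD and WT without treatment asks, if the labels hold, what the knockdown alone changed. No gene differed past the threshold between these labels. The smallest p belonged to Eya4, a transcriptional coactivator, Syngr1, a synaptic vesicle protein, and Cd22, a B cell receptor, which were higher by 0.42, 0.78 and 0.64 (log2) in libraries labelled SETD2 KD with limma adjusted p of 0.127, 0.140 and 0.153. Each passed in other fits. Syngr1 did with library weights (0.000203), tissue list means as covariates (7.71e-05), without the 5 doubted libraries (0.0125) and with only the groups compared (0.0310). Cd22 passed in 3 of these 4 (0.00247 with weights, 0.0393 with covariates, 0.0325 with only the groups compared), and Eya4 with weights (0.00138), covariates (0.0409), quantile normalisation (0.0243) and no variance trend (0.0492). Fn1, which encodes fibronectin, differed by -0.55 and the secreted protein gene Mucl1 by -1.31, both with an adjusted p of 1.00, and both passed with library weights (-0.58, 0.0329 and -1.31, 0.0349). Setd2 differed by -0.02 ± 0.09 (log2, SE), Atr by -0.04 ± 0.09, Chek1 by -0.02 ± 0.08, Cgas by -0.15 ± 0.12 and Tmem173, which encodes STING, by 0.14 ± 0.07, each with an adjusted p of 1.00. Limma called 0 of 15916 genes, 512 had an unadjusted p under 0.05, and the same tool called 11 genes with library weights. Without SETD2 KD untreated replicate 1 it called 1 gene, Eya4 (adjusted p 0.0399), and 1 list passed, replication (0.10, exact permutation test, adjusted p 0.0429). Genes changed by 0.5 and 1 (log2) in simulated data of this comparison, with 1 spread per gene for all groups, were recovered in 90% and 99% of cases. No gene list differed (exact permutation test, 0 of 34 lists). The nearest were the histone list, 0.13 higher (adjusted p 0.0991), the replication list, 0.08 higher (0.129), and the red blood cell list, -0.83 (0.172). Camera with its preset correlation called 8 lists and camera with an estimated correlation 0. The type I interferon, interferon-gamma, T cell and cGAS-STING lists differed by 0.03, 0.09, 0.04 and -0.00, and 0 of their 37, 18, 14 and 12 measured members passed, over all genes or adjusted over the list alone.

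In libraries labelled WT, VE822 went with a large rise of Igf2, the fetal growth factor, and of a set of genes that were low in untreated tumours, together with higher T cell and MHC class II transcripts and lower cholesterol synthesis transcripts. These 3 list calls did not hold by camera with an estimated correlation (adjusted p 0.768 each) or without the 5 doubted libraries (exact permutation test, adjusted p 0.116, 0.135 and 0.116). Igf2 (ENSMUSG00000048583, chromosome 7, 142650766 to 142666816, minus strand) went from 5.92 ± 0.08 (SD, n = 7) to 10.27 ± 0.75 (SD, n = 6), a rise of 4.34 ± 0.53 (log2, SE; limma adjusted p 2.04e-06). Aoc1, the diamine oxidase that degrades histamine, rose by 3.79 ± 0.45, the cytochrome P450 Cyp4f40 by 3.28 ± 0.40, the neuronal kinesin Kif1a by 3.21 ± 0.34 and the mast cell tryptase Tpsab1 by 3.20 ± 0.43. Ptgds, a prostaglandin D synthase, Myom2, a protein of the muscle sarcomere, and Lct, lactase, rose by 2.92, 2.72 and 2.67. Cyp2f2 (ENSMUSG00000052974, chromosome 7, 27119909 to 27133660, plus strand), a xenobiotic-metabolising cytochrome P450, fell by 2.82 on the log2 scale, from 9.09 ± 0.58 to 6.28 ± 0.46 (adjusted p 2.8e-08).

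In libraries labelled WT VE822, the nephron transcription factor gene Pou3f3 changed by -2.08 ± 0.27, Hsd11b2, which inactivates glucocorticoids, by -2.05 ± 0.22, the methyltransferase gene Inmt by -1.64 ± 0.22 and the carboxylesterase gene Ces2g by -1.59 ± 0.13. The potassium channel gene Kcnk5 changed by -1.40, the BMP antagonist gene Chrdl2 by -1.40 and Slc16a4, a monocarboxylate transporter gene, by -1.39 ± 0.08 (adjusted p 8.25e-11). Of 15916 genes, 5530 passed, 2737 higher and 2793 lower, and 282 of them changed at least 2-fold. With the median of each chromosome removed from each library, an alternative chosen after the data were seen, the calls split into 3266 higher and 2032 lower. Setd2 fell by 0.80 ± 0.09 (adjusted p 1.19e-06). Atr differed by -0.06 (0.630), Cgas by 0.20 (0.208) and Tmem173 by -0.02 (0.848). Chek1 fell by 0.25 (0.0221), a call that ended without WT VE822 replicate 2 (-0.19, 0.0727), with tissue list means as covariates (-0.16, 0.248) and without the 5 doubted libraries (-0.09, 0.479).

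The T cell, MHC class II, checkpoint, dendritic, cytotoxic and MHC class I lists were higher in libraries labelled WT VE822, whereas the macrophage, neutrophil, B cell and type I interferon lists did not pass. The T cell list mean went from 4.78 ± 0.18 (SD, n = 7) to 5.63 ± 0.42 (SD, n = 6), higher by 0.85 (exact permutation test, adjusted p 0.0198). Of its 14 measured members 12 rose, 13 when adjusted over the list alone. Among them were the costimulatory receptor Cd28 by 1.98, the adhesion receptor Cd2 by 1.02, Icos by 0.95 and the kinase Lck by 0.52. Cd28 did not follow the list mean within WT VE822 libraries. It was highest in replicate 3 (7.57), where the list mean was lowest (5.13). The MHC class II list was higher by 0.73 (0.0198), with 8 of 10 members risen (10 adjusted over the list alone), H2-Aa by 1.08 and H2-Ab1 by 1.02. The checkpoint list was higher by 0.50 (0.0198), with 10 of 12 risen (10 adjusted over the list alone), Ctla4 by 1.01 and Tigit by 0.68. The dendritic cell list was higher by 0.56 (0.0264), with 7 of 11 risen (8 adjusted over the list alone), Ccr7 by 1.17 and Itgax by 0.95. The cytotoxic and NK cell list was higher by 0.59 (0.0347), with 9 of 11 risen (11 adjusted over the list alone), Nkg7 by 0.89 and Klrb1c by 0.48. The MHC class I list was higher by 0.25 (0.0347), with 7 of 18 risen (8 adjusted over the list alone), B2m by 0.33. With camera and an estimated correlation the adjusted p was 0.849 for MHC class I and 0.768 for the other 5 of these lists.

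The 3 list calls with the largest p lay near the threshold, and each was lost without any 1 of several libraries. In those settings the difference was 0.21 to 0.26 for MHC class I and 0.47 to 0.59 for the cytotoxic list. For the dendritic list it was 0.47 to 0.55. Leaving out a library also raises the smallest p this test can give. MHC class I and the cytotoxic list each lost their call without any 1 of 9 libraries (WT untreated replicates 2, 3, 4, 5, 6 and 7 and WT VE822 replicates 2, 4 and 5), with adjusted p of 0.0526 to 0.0736 and 0.0525 to 0.0899 in the exact permutation test. The dendritic list lost its call without WT untreated replicate 2, 3, 5 or 6 or WT VE822 replicate 4 (0.0501 to 0.0613). The number of lists past the threshold was 5 without any 1 of those 5 libraries and 13 without WT VE822 replicate 6. Without the 5 doubted libraries, which leaves 6 against 3, none of the 8 calls held, and the smallest p possible is then 0.0119. The differences in that setting were 0.85 for T cells (adjusted p 0.116), 0.72 for MHC class II (0.135), 0.43 for checkpoints (0.116), 0.53 for dendritic cells (0.147), 0.53 for the cytotoxic list (0.147), 0.27 for MHC class I (0.116), -0.51 for cholesterol synthesis (0.116) and 0.21 for histones (0.135).

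The interferon-gamma and chemokine list was higher by 0.85 in libraries labelled WT VE822 but did not pass (exact permutation test, adjusted p 0.0515), although 11 of its 18 measured members rose over all genes and 14 adjusted over the list alone. It passed without WT untreated replicate 1 (1.01, adjusted p 0.0123), whose list mean of 8.79 lay above the 7.50 to 7.84 of the other 6, and without WT VE822 replicate 1 (0.0429) or 3 (0.0268). The type I interferon list differed by 0.03 (0.760), with 4 of 37 members risen and 3 fallen, or 4 and 2 adjusted over the list alone. Usp18, a brake on interferon signalling, rose by 0.48 and Bst2, tetherin, by 0.44. Stat2, on chromosome 10, fell by 0.32 and lost that call with chromosome medians removed (-0.06, limma adjusted p 0.640). The cGAS-STING list differed by 0.05 (0.238), with 2 of 12 members risen and 1 fallen, or 1 and 1 adjusted over the list alone. Rnaseh2c, a subunit of ribonuclease H2, rose by 0.31. The kinase gene Tbk1, on chromosome 10, fell by 0.22 with the deposited values and was at 0.04 in the opposite direction with chromosome medians removed.

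Cholesterol synthesis transcripts were lower in libraries labelled WT VE822. The list mean went from 11.04 ± 0.15 (SD, n = 7) to 10.46 ± 0.22 (SD, n = 6), a difference of -0.58 (exact permutation test, adjusted p 0.0198), and 15 of 15 members fell, over all genes and adjusted over the list alone. The sterol carrier Stard4 fell by 0.88, Dhcr7, the last enzyme of the pathway, by 0.72, and Sqle and Lss by 0.66 each. The list of histone genes with polyadenylated transcripts was higher by 0.23 (0.0198), with 4 of 8 members risen in both adjustments, Hist2h2be by 0.62. With an estimated correlation the camera adjusted p was 0.768 for cholesterol synthesis and 0.849 for the histone list. The mitotic list differed by 0.08 (0.329), with 6 of 20 risen (5 adjusted over the list alone), Birc5 by 0.33 and Cdca8 by 0.28. The p53 list differed by -0.02 (0.654), with 3 of 19 risen and 6 fallen, or 5 and 8 adjusted over the list alone, and passed when the median over members was taken (-0.13, adjusted p 0.0255). Sesn1, on chromosome 10, fell by 0.68. Eda2r rose by 0.98, a call lost without the 5 doubted libraries (0.51, limma adjusted p 0.0796).

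The remaining lists did not pass between libraries labelled WT VE822 and WT untreated in the exact permutation test. Among markers of other cell types, the list mean differed by 1.34 for skeletal muscle (adjusted p 0.193), 0.72 for fibroblasts (0.0960), 0.46 for adipocytes (0.512), 0.34 for keratinocytes (0.0515, 2 members measured), 0.27 for red blood cells (0.527), 0.27 for B cells (0.0648), 0.26 for neutrophils (0.329), 0.25 for endothelium (0.380) and -0.10 for macrophages (0.469). Among the pathway lists it differed by -0.15 for hypoxia (0.407), -0.11 for the histone methylation list that holds Setd2 (0.155), 0.10 for mesenchymal transition (0.527), -0.09 for renal epithelial identity (0.119), -0.08 for the stress and unfolded protein response (0.119) and 0.08 for oxidative phosphorylation (0.329). It differed by -0.07 for ATR-CHK1 (0.0726), -0.05 for homologous recombination (0.469), 0.05 for ribosomal proteins (0.527), 0.04 for mitochondrial transcripts (0.760), 0.03 for replication (0.459) and -0.02 for NF-kB targets (0.874). Of these lists, B cells passed without WT untreated replicate 1 (0.0368) or WT VE822 replicate 1 (0.0429), ATR-CHK1 without WT untreated replicate 1 (0.0401) or WT VE822 replicate 6 (0.0322), and keratinocytes without WT VE822 replicate 5 (0.0343) or 6 (0.0358). Without WT VE822 replicate 1, renal epithelial identity (0.0343) and oxidative phosphorylation (0.0215) passed, and without WT VE822 replicate 6 fibroblasts (0.0172), the stress response (0.0358) and histone methylation (0.0334). Skeletal muscle transcripts moved with single libraries: the muscle list mean was 8.93, 6.80 and 7.58 in WT VE822 replicates 1, 2 and 4 and 6.5 in WT untreated replicate 4.

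**Figure D2:**
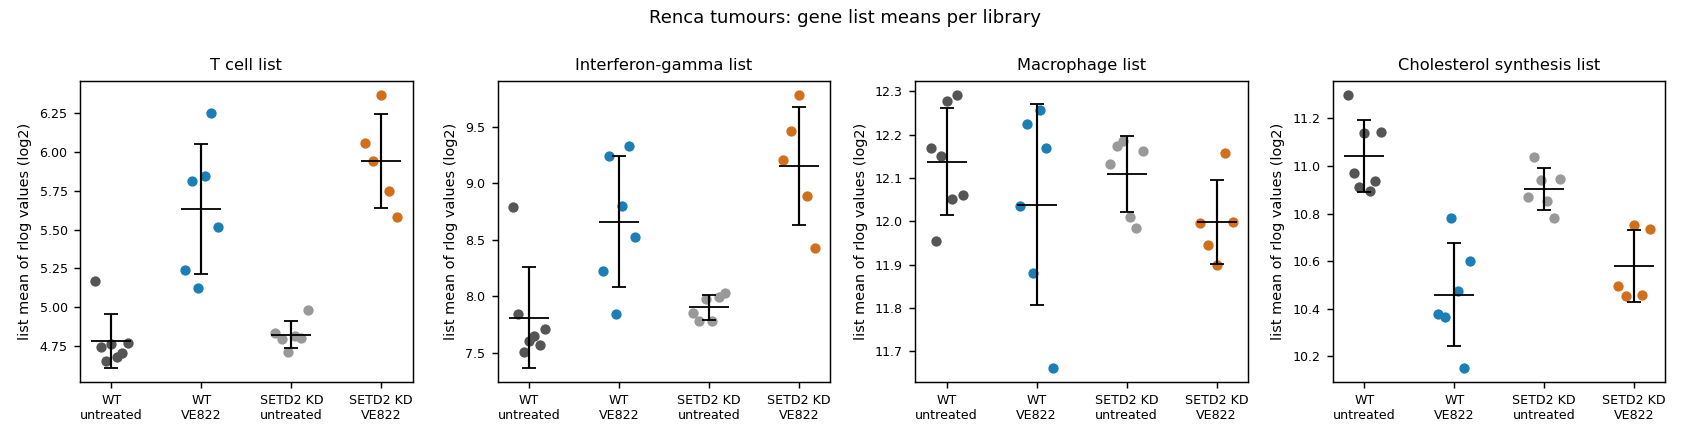
Means of rlog values (log2) over the members of the T cell, interferon-gamma and chemokine, macrophage and cholesterol synthesis lists in each mouse library; points are libraries, the horizontal line is the group mean and the bars are 1 SD. The T cell mean was 4.78 and 4.82 in the untreated labels and 5.63 and 5.94 in the VE822 labels, whereas the macrophage mean differed by -0.10 and -0.11 between the VE822 and untreated labels.

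Genes of whole chromosomes moved with the VE822 label. Over 477 genes of chromosome 10 with a mean rlog of at least 8, the median change in libraries labelled WT was -0.26 and 89.5% of the genes were lower (exact permutation test on the per-library medians, adjusted p 0.00167, n = 7 and 6). The median was -0.12 over 553 genes of chromosome 8 and 0.13 over 471 genes of chromosome 6, with the same adjusted p. Of 20 chromosomes, 12 passed in libraries labelled WT, 2 in libraries labelled SETD2 KD, and 0 between genotype labels without treatment or under VE822. In libraries labelled SETD2 KD the medians were -0.19 for chromosome 10 (adjusted p 0.0693), -0.12 for chromosome 8 (0.0216), -0.10 for chromosome 15 (0.0216) and 0.04 for chromosome 6 (0.606). On chromosome 6 SETD2 KD VE822 replicate 4 stood at -0.20, whereas the other 4 libraries of its group lay between 0.03 and 0.11.

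**Figure D3:**
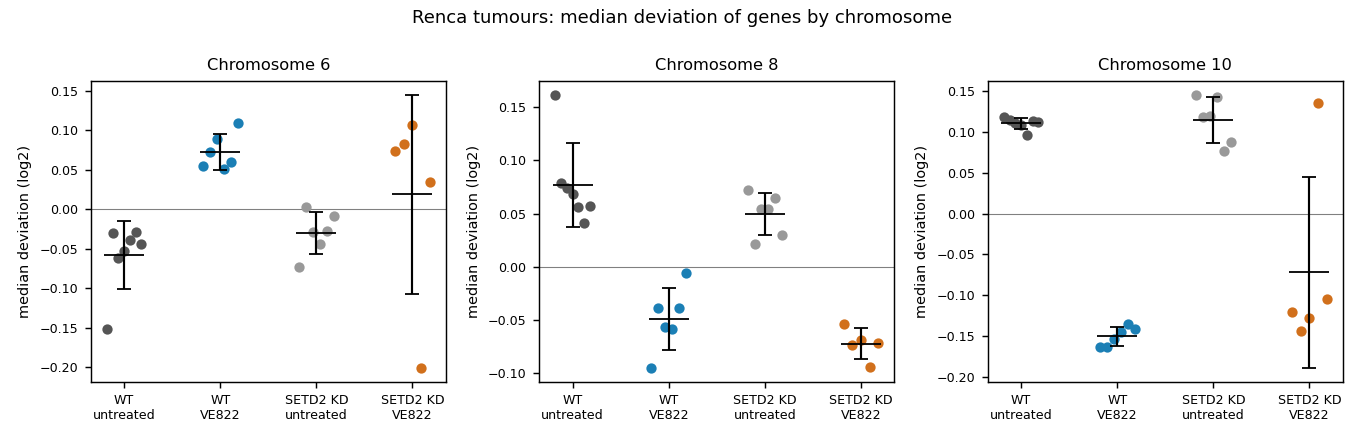
Median deviation (log2) of genes on chromosomes 6, 8 and 10 from their mean over all mouse libraries, in each library; points are libraries, the horizontal line is the group mean and the bars are 1 SD. On chromosome 10 the WT VE822 mean was -0.15 against 0.11 in WT untreated, and SETD2 KD VE822 replicate 4 stood at 0.14 while the other 4 libraries of its group lay between -0.14 and -0.10.

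In libraries labelled SETD2 KD, VE822 went with many of the changes seen in libraries labelled WT, higher T cell and lower cholesterol synthesis transcripts among them. By camera with an estimated correlation, which compares a list with the other genes, neither list call held (adjusted p 0.363 and 0.627). The cholesterol call also ended with the median over members (exact permutation test, adjusted p 0.115). Igf2 rose by 4.14 ± 0.58 (log2, SE; limma adjusted p 2.3e-05), Aoc1 by 3.55 ± 0.48, Tpsab1 by 3.03 ± 0.46 and the T cell-attracting chemokine Cxcl9 by 2.90 ± 0.52. Tceal7, Myom2, Kif1a and Cd28 rose by 2.72, 2.56, 2.51 and 2.40. Cyp2f2 fell by 2.58 ± 0.27, the sodium pump regulator Fxyd6 (ENSMUSG00000066705, chromosome 9, 45370185 to 45396159, plus strand) fell by 1.88 ± 0.11, Ces2g fell by 1.80 and Slc16a4 fell by 1.67. Avil, an actin-binding protein, and Ptprr, a tyrosine phosphatase, both on chromosome 10, fell by 1.57 and 1.39, and Chrdl2 and Hsd11b2 fell by 1.54 and 1.47.

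Past the threshold in libraries labelled SETD2 KD were 3540 of 15916 genes, 1688 higher and 1852 lower, and with chromosome medians removed the split was 2043 higher and 1340 lower. Setd2 fell by 1.09 ± 0.10 (limma adjusted p 1.08e-07). Atr differed by 0.09 (0.529), Chek1 by -0.07 (0.615), Cgas by 0.34 (0.0623) and Tmem173 by -0.06 (0.675). Cgas passed without SETD2 KD untreated replicate 6 (0.0326) or SETD2 KD VE822 replicate 1 (0.0275) or 3 (0.0468). It also passed with tissue list means as covariates (0.31, limma adjusted p 0.0406). SETD2 KD VE822 replicate 4 stood apart from its group, with Igf2 at 6.37, Aoc1 at 5.41, Kif1a at 7.44 and Cd28 at 5.44. Its Setd2 value of 9.96 lay with the other libraries labelled VE822, and without it 4439 genes passed.

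The interferon-gamma and chemokine list mean went from 7.90 ± 0.11 (SD, n = 6) to 9.15 ± 0.52 (SD, n = 5) in libraries labelled SETD2 KD, higher by 1.25 (exact permutation test, adjusted p 0.0105). Of its 18 measured members 16 rose, over all genes and adjusted over the list alone, the GTPase Gbp4 by 2.20, Cxcl10 by 1.63 and Ciita, the master regulator of MHC class II, by 1.40. The T cell list was higher by 1.12 (0.0105), with 13 of 14 risen (14 adjusted over the list alone), Cd3g by 1.41, Cd2 by 1.14 and Cd6 by 1.13. The cytotoxic and NK cell list was higher by 0.77 (0.0105), with 11 of 11 risen in both adjustments, Nkg7 by 1.37 and perforin, Prf1, by 0.86. MHC class II was higher by 0.85 (0.0105), with 7 of 10 risen (9 adjusted over the list alone), H2-Aa by 1.27 and Cd74 by 1.1. With camera and an estimated correlation the adjusted p was 0.363 for these 4 lists.

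The checkpoint list was higher by 0.63 in libraries labelled SETD2 KD VE822 (exact permutation test, adjusted p 0.0105), with 7 of 12 risen (10 adjusted over the list alone), Pdcd1, which encodes PD-1, by 1.39, Lag3 by 1.08, Ctla4 by 0.89 and Tigit by 0.85. The dendritic cell list was higher by 0.57 (0.0105), with 8 of 11 risen in both adjustments, Xcr1 by 0.83, Itgax by 0.79 and Clec9a by 0.65. With an estimated correlation the camera adjusted p was 0.363 for the checkpoint list and 0.543 for the dendritic list. MHC class I differed by 0.33 (0.120), with 10 of 18 risen (13 adjusted over the list alone) and B2m higher by 0.44. It passed without SETD2 KD VE822 replicate 4 (0.44, adjusted p 0.0180). The type I interferon list differed by 0.22 (0.123), with 8 of 37 risen in both adjustments, Oasl2 by 0.85 and Bst2 by 0.68, and it passed without SETD2 KD VE822 replicate 5 (0.31, adjusted p 0.0202). The cGAS-STING list differed by 0.12 (0.125), with 3 of 12 risen and 1 fallen, or 4 and 3 adjusted over the list alone. The nucleic acid sensor Zbp1 rose by 1.00 and Rnaseh2c by 0.28. The latter call was lost without SETD2 KD VE822 replicate 5 (limma adjusted p 0.0504) and with tissue list means as covariates (0.19, 0.0856).

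Cholesterol synthesis was lower in libraries labelled SETD2 KD VE822 by -0.33 (exact permutation test, adjusted p 0.0105), with 7 of 15 members fallen (10 adjusted over the list alone). Stard4 fell by 0.88, Sqle by 0.44, Mvd by 0.44 and Lss, on chromosome 10, by 0.37, the last lost with chromosome medians removed (-0.18, limma adjusted p 0.191). With an estimated correlation the camera adjusted p was 0.627, and with the median over members the list did not pass (-0.22, adjusted p 0.115). The red blood cell list was higher by 0.82 (0.0184), with 0 of 6 members past the limma threshold over all genes and 6 risen adjusted over the list alone, and Hbb-bt, a beta-globin gene with near-identical copies, at 0.67. This list had a camera adjusted p of 0.664 with an estimated correlation and lost its call without SETD2 KD untreated replicate 1, 3, 4, 5 or 6 (adjusted p 0.0600 to 0.0675). The mitotic list differed by 0.03 (0.848), with 0 of 20 risen and 1 fallen in both adjustments. That member, Cdk1, on chromosome 10, differed by -0.20, and by -0.01 with chromosome medians removed (limma adjusted p 0.884). The p53 list differed by -0.06 (0.217), with 0 of 19 risen and 5 fallen, or 3 and 6 adjusted over the list alone, and passed with the median over members (-0.17, exact permutation test, adjusted p 0.0460). Its members Sesn1 and Zmat3 differed by -0.63 and -0.25. Zmat3 lost its call with tissue list means as covariates (-0.22, limma adjusted p 0.0545).

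The other lists did not pass between libraries labelled SETD2 KD VE822 and SETD2 KD untreated in the exact permutation test. Among cell types, the list mean differed by 0.93 for adipocytes (adjusted p 0.217), 0.52 for fibroblasts (0.168), 0.29 for B cells (0.103), -0.28 for skeletal muscle (0.250), 0.22 for endothelium (0.565), 0.14 for neutrophils (0.660), -0.11 for macrophages (0.198) and 0.05 for keratinocytes (0.905). It differed by -0.20 for hypoxia (0.478), 0.18 for mitochondrial transcripts (0.198), 0.10 for histones (0.534), -0.08 for the stress response (0.103), 0.06 for NF-kB targets (0.678), 0.06 for mesenchymal transition (0.660) and -0.06 for ATR-CHK1 (0.298). For replication it differed by -0.06 (0.250), with 9 of 21 members fallen and 2 risen in both adjustments. It differed by -0.04 for homologous recombination (0.694), histone methylation (0.509) and ribosomal proteins (0.660), by 0.01 for oxidative phosphorylation (0.905) and by -0.00 for renal epithelial identity (0.935). Adipocytes passed without SETD2 KD untreated replicate 6 (1.15, adjusted p 0.0337), fibroblasts without SETD2 KD VE822 replicate 3 (0.70, 0.0360), B cells without SETD2 KD VE822 replicate 4 (0.0442) or 5 (0.0486) and histones without replicate 4 (0.21, 0.0180). With the median over members, macrophages (-0.22, 0.0491) and endothelium (0.63, 0.0210) passed.

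The changes under VE822 in the 2 genotype labels went together across genes. Over 15916 genes the log2 fold changes had a Pearson r of 0.834 and a Spearman rho of 0.749, described without a p because genes are not independent replicates. The 2 comparisons share no library, but their calls take each gene's variance from the same model. Calls can coincide through that shared variance, so the counts given for independent lists are only a rough reference. Of the genes that rose, 1248 were called in both labels, against 290 for independent lists of those sizes, and of those that fell 1357, against 325. No gene was called in opposite directions, and 93.7% of the calls in libraries labelled WT had the same sign in libraries labelled SETD2 KD.

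Libraries labelled SETD2 KD and WT under VE822 differed in 2 genes past the threshold. Fmod (ENSMUSG00000041559, chromosome 1, 134037254 to 134048277, plus strand), the collagen-binding proteoglycan fibromodulin, was at 7.44 ± 0.20 (SD, n = 5) in libraries labelled SETD2 KD VE822 and 9.05 ± 0.51 (SD, n = 6) in those labelled WT VE822, a difference of -1.61 ± 0.22 (log2, SE; limma adjusted p 0.00236). Mfsd12 (ENSMUSG00000034854, chromosome 10, 81357491 to 81366225, plus strand), a lysosomal transporter gene, was higher by 0.32 ± 0.05 (0.00523), a call lost with chromosome medians removed (0.24, adjusted p 0.0614), quantile normalisation (0.0614), covariates (0.0602), without the 5 doubted libraries (0.183) and with only the groups compared (0.839). Fmod also lost its call with only the groups compared (-1.61). Parm1, Fn1, Mgam and Plxna2 followed without passing, at 0.22, -0.82, -0.99 and 0.43, each with an adjusted p of 0.0535. All 4 passed without WT VE822 replicate 3 (0.0328, 0.0303, 0.0347 and 0.0367). Fn1, Mgam and Plxna2 passed without SETD2 KD VE822 replicate 1 (0.0395, 0.0353 and 0.0353), Parm1 and Mgam without WT VE822 replicate 1 (0.0141 and 0.0172), Fn1 without WT VE822 replicate 5 (0.0458) or SETD2 KD VE822 replicate 5 (0.0302), and Mgam without SETD2 KD VE822 replicate 3 (0.0399). Setd2 differed by -0.31 ± 0.10 (adjusted p 0.225), Atr by 0.11 (0.621), Chek1 by 0.16 (0.468), Cgas by -0.01 (0.980) and Tmem173 by 0.11 (0.578). At an unadjusted p under 0.05 there were 2031 genes. No list passed (exact permutation test, 0 of 34). The interferon-gamma list differed by 0.49 (0.736), the T cell list by 0.31 (0.736), the type I interferon list by 0.22 (0.736), the cGAS-STING list by 0.07 (0.736) and the skeletal muscle list by -1.70 (0.736). Over all genes 0 members of these lists passed, and adjusted over the list alone 9 of 37 type I interferon and 1 of 12 cGAS-STING members were higher and 11 of 11 muscle members lower. Camera called 11 lists with its preset correlation and 0 with an estimated one. Without WT VE822 replicate 3, 46 genes passed, without SETD2 KD VE822 replicate 1 24, without WT VE822 replicate 1 11 and without WT VE822 replicate 5 6.

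The interaction term asks, on the log2 scale, whether the VE822 change differed between the genotype labels. The series title speaks of synergy, which need not mean such a difference in transcripts. No gene and no list passed. The smallest p belonged to Plxna2, a semaphorin receptor (0.54 ± 0.11), Fmod (-1.34 ± 0.30) and Pkhd1, the fibrocystin gene of renal epithelium (0.83 ± 0.19), each with a limma adjusted p of 0.424. Setd2 was at -0.29 ± 0.14 (adjusted p 0.544), Atr at 0.15 (0.727), Chek1 at 0.18 (0.659), Cgas at 0.14 ± 0.17 (0.822) and Tmem173 at -0.03 ± 0.11 (0.949). Limma called 0 of 15916 genes, with 1452 at an unadjusted p under 0.05 and 0 under each other setting of the same tool. Simulated interactions of 0.5 and 1 (log2), drawn with 1 spread per gene for all groups, were recovered in 54% and 85% of cases. Smaller ones could pass undetected, and recovery may be lower for genes that spread more in VE822 labels. In limma on the list means, the cGAS-STING list had an interaction of 0.07 (adjusted p 0.865), the type I interferon list 0.19 (0.865), the interferon-gamma list 0.40 (0.865), the T cell list 0.27 (0.865) and the cholesterol list 0.26 (0.865), with 0 members of these lists past over all genes and 2 of 15 cholesterol members adjusted over the list alone. Camera called 6 lists with its preset correlation and 0 with an estimated one.

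Libraries labelled SETD2 KD VE822, set against libraries labelled WT untreated, showed the combined change of both labels. Igf2 was higher by 4.28 ± 0.56 (log2, SE; limma adjusted p 8.28e-06), Aoc1 by 3.56, Cxcl9 by 3.27, Kif1a by 2.91, Tpsab1 by 2.87, Atp13a4, a cation-transporting ATPase gene, by 2.73, Tceal7 by 2.69 and Ptgds by 2.68. Cyp2f2 fell by 2.72 ± 0.27, Ces2g by 1.93, Hsd11b2 by 1.86, Fxyd6 fell by 1.75, Slc16a4 by 1.64, Avil by 1.54, the arachidonic acid epoxygenase Cyp2j6 by 1.45 and Mucl1 fell by 1.44. Setd2 fell by 1.11 ± 0.10 (4.75e-08). Atr differed by 0.05 (0.731), Chek1 by -0.10 (0.478), Cgas by 0.18 (0.314) and Tmem173 by 0.09 (0.478), which passed without SETD2 KD VE822 replicate 4 (0.18, adjusted p 0.0388). Of 15916 genes 3890 passed, 1922 higher and 1968 lower, against 2207 higher and 1469 lower with chromosome medians removed.

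For the combined change, 8 lists passed the exact permutation test. The interferon-gamma list was higher by 1.34 (adjusted p 0.0107), with 16 of 18 members risen in both adjustments, Gbp4 by 2.27, Cxcl10 by 1.85 and Ciita by 1.48. The T cell list was higher by 1.16 (0.00715), with 14 of 14 risen in both adjustments, Cd28 by 2.47 and Cd3g by 1.42. Cd28 did not follow the list mean in SETD2 KD VE822 replicate 4. There it was at 5.44 (7.58 to 7.97 in the rest of the group), whereas the list mean was 5.75 (5.58 to 6.37). The cytotoxic list was higher by 0.82 (0.00715, 11 of 11 in both adjustments), MHC class II by 0.82 (0.00715, 9 of 10 in both adjustments), the dendritic list by 0.65 (0.00715, 6 of 11, 9 adjusted over the list alone) and the checkpoint list by 0.64 (0.00715, 10 of 12 in both adjustments). Cholesterol synthesis was lower by -0.46 (0.00715), with 13 of 15 fallen (15 adjusted over the list alone), and the stress and unfolded protein response by -0.13 (0.0107), with 5 of 16 fallen in both adjustments. The latter call was lost with chromosome medians removed (-0.08, adjusted p 0.0644), and the dendritic call with the median over members (0.52, 0.0715). The p53 list passed with the median over members (-0.10, 0.0386). With camera and an estimated correlation the adjusted p was 0.295 for the interferon-gamma, T cell, cytotoxic, MHC class II, checkpoint and cholesterol lists, 0.373 for the dendritic list and 0.383 for the stress response list. Without SETD2 KD VE822 replicate 4, 13 lists passed. MHC class I differed by 0.38 (0.0525), with 13 of 18 risen (17 adjusted over the list alone), B2m by 0.54. It passed without WT untreated replicate 1 (adjusted p 0.0268) or SETD2 KD VE822 replicate 4 (0.0206) or 5 (0.0468), and with libraries centred (0.0472), members scaled (0.0472) or chromosome medians removed (0.0429). The type I interferon list differed by 0.25 (0.0787), with 11 of 37 risen (13 adjusted over the list alone), and passed without SETD2 KD VE822 replicate 5 (0.0114). The cGAS-STING list differed by 0.12 (0.0687), with 2 of 12 risen and 3 fallen, or 3 and 3 adjusted over the list alone, Zbp1 by 1.05. It passed without WT untreated replicate 1 (0.0245) or SETD2 KD VE822 replicate 4 (0.0281) or 5 (0.0309), with libraries centred (0.0429) and with chromosome medians removed (0.0215). The list of mitochondrial transcripts, a sign of RNA and library quality, was also higher, by 0.26 (0.0991), and passed without WT untreated replicate 1 (0.31, 0.0268). B cells (0.31, 0.0787) passed without WT untreated replicate 1 (0.0491) or SETD2 KD VE822 replicate 4 (0.0476), and without the latter histones (0.34, 0.0129) and histone methylation (-0.09, 0.0429) passed too. Without the 5 doubted libraries, MHC class I (0.0294), cGAS-STING (0.0294), histones (0.0231) and keratinocytes (0.0405) passed.

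In 786-O cells given the CHK1 inhibitor, NF-kB target, histone and ribosomal protein lists were higher, and replication, homologous recombination, cholesterol synthesis and histone methylation lists lower, by camera with its preset correlation. None of these 7 calls held with an estimated correlation (adjusted p 0.841). With 2 libraries per group that variant has few degrees of freedom, so it cannot decide whether the calls hold. The short-chain dehydrogenase DHRS2 rose by 5.49 ± 0.15 (log2, SE; limma adjusted p 0.0232), the neutrophil chemokine CXCL8 by 5.46 ± 0.73 (0.0325), the lipoxygenase ALOXE3 by 5.36 ± 0.52 (0.0246) and the cytokine IL11 by 5.14 ± 0.32 (0.0232). PPP1R15A, which ends the integrated stress response, rose by 4.61 ± 0.11, from 9.46 ± 0.13 to 14.08 ± 0.12 (SD, n = 2 each), the dynein DNAH17 by 4.33, the growth arrest gene GADD45A by 4.14 ± 0.11 and the keratin-associated KRTAP2-3 by 3.98. The calcium channel subunit TMEM37 fell by 3.47, KLHL14 by 3.29, the axon guidance protein SEMA5B by 3.25, the potassium channel KCNJ16 fell by 3.19, the p38 kinase activator MAP2K6 by 3.14, PALM3 by 3.08, the transporter scaffold PDZK1 by 3.06 and the tight junction protein CLDN2 by 3.04. With a robust prior CXCL8 (limma adjusted p 0.0835), DNAH17 and CLDN2 lost their calls. Some of these genes had few recovered counts in 1 group: PALM3 1 in each treated library, MAP2K6 4 and 3 treated, DHRS2 3 and 2 untreated and ALOXE3 3 and 4 untreated. Their changes are understated or imprecise at this depth.

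Of the genes in the pathway under study in 786-O cells, CHEK1 itself fell by 0.40 ± 0.07 (limma adjusted p 0.0461) and MB21D1, which encodes cGAS, rose by 0.87 ± 0.13 (0.0390). SETD2 differed by -0.11 ± 0.06 (0.308), ATR by 0.42 ± 0.16 (0.18) and TMEM173 by -1.0 ± 0.19 (0.0565). Of 29353 genes tested 3878 passed, 2069 higher and 1809 lower, 1709 of them at least 2-fold. The split by direction depends on single libraries, with 2925 higher and 708 lower without CHK1 inhibitor replicate 1 and 3901 higher and 757 lower without replicate 2. The count rests on the 2 untreated libraries: without either of them limma called 0 genes, with 7268 (without replicate 1) and 6882 (without replicate 2) at an unadjusted p under 0.05, so none of the 63 calls among the 72 genes the naming rule gives holds in these 2 fits. Without CHK1 inhibitor replicate 1 or 2 it called 3633 and 4658, of which 802 and 926 were among the 3878 in the same direction, and 46 and 42 of those 63 calls were lost. Voom on the recovered counts, chosen after the data were seen, called 6416 and 6450 genes under 2 scalings. In simulated data with 100 changed genes of each size, changes of 1 and 2 (log2) were recovered in 6% and 35% of cases. Changes of that size can thus be missed where few genes change. Many more genes passed in the real data, which makes the adjustment over genes milder, so these shares do not measure its power.

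**Figure D4:**
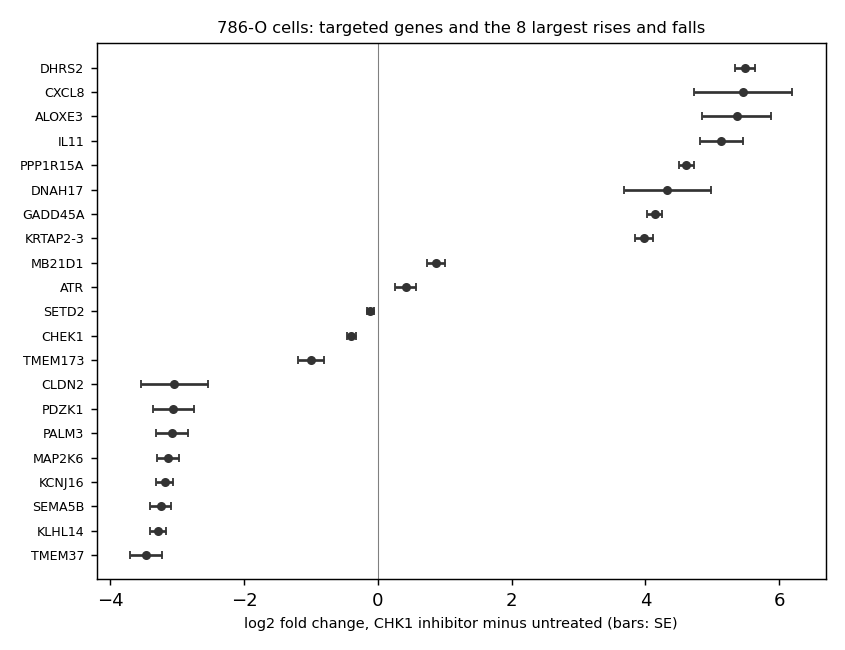
Log2 fold change of the targeted genes and of the 8 largest rises and 8 largest falls in 786-O cells, CHK1 inhibitor minus untreated (n = 2 each); points are limma estimates and bars are SE. DHRS2, CXCL8, ALOXE3 and IL11 lay above 5 and TMEM37 at -3.47, while SETD2 lay at -0.11.

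The 786-O lists that were higher were NF-kB targets, histone genes and ribosomal proteins. Among NF-kB targets 12 of 21 measured members rose and 0 fell, or 15 and 2 adjusted over the list alone (camera adjusted p 6.13e-05 with its preset correlation), CSF2 by 2.42 (from 3 and 4 recovered counts untreated), IL6 by 2.37, CXCL3 by 1.40 and the adhesion molecule ICAM1 by 1.24. The p53 list had 5 of 22 members risen and 2 fallen in both adjustments and did not pass (0.719). The cell cycle inhibitor CDKN1A rose by 2.26, the pro-apoptotic PMAIP1 by 2.09, AEN by 1.81 and SESN2 by 1.65. In the histone list 5 of 10 rose (9 adjusted over the list alone, 3.22e-05), HIST1H2AC by 3.87, HIST1H1C by 2.90, HIST1H2BK by 2.10 and HIST1H2BD by 1.72, genes of a family with similar copies. Ribosomal protein genes rose in 11 of 15 cases (14 adjusted over the list alone, 1.89e-06), RPL18 by 0.77, RPS9 by 0.73, RPL8 by 0.56 and RPL4 by 0.54. With camera and an estimated correlation the adjusted p was 0.841 for the NF-kB, histone and ribosomal lists. That variant has few degrees of freedom for so few libraries.

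The DNA replication list was lower in 786-O cells given the CHK1 inhibitor, with 10 of 21 members fallen and 0 risen, or 16 and 0 adjusted over the list alone (camera adjusted p 3.74e-06). CDC45, MCM6 and the sliding clamp gene PCNA fell by 0.95 each and MCM3 by 0.86. In the homologous recombination list 5 of 13 fell (7 adjusted over the list alone, 7.37e-05), FANCD2 by 1.47, BLM by 0.94 and XRCC2 by 0.78. In the cholesterol synthesis list 4 of 15 fell (10 adjusted over the list alone, 2.05e-06), STARD4 by 1.40, HMGCS1 by 1.37 and FDPS by 0.47. In the histone methylation list that holds SETD2, 4 of 15 fell and 1 rose, or 8 and 1 adjusted over the list alone (0.00783), PSIP1 by 0.74, NSD1 and MSH6 by 0.72 each and KDM4B by 0.65. With an estimated correlation, and so few degrees of freedom, the camera adjusted p was 0.841 for these 4 lists. Of all 34 lists fry called 4 (cGAS-STING, hypoxia, the histone methylation list and ribosomal proteins).

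Interferon and antigen presentation genes of 786-O cells went both ways. The type I interferon list had 1 of 38 members risen and 4 fallen in both adjustments (camera adjusted p 0.877): OASL rose by 1.91, whereas STAT2 and PARP14 fell by 1.01 and 0.44. The cGAS-STING list had 2 of 12 risen and 1 fallen, or 5 and 3 adjusted over the list alone (0.911), the DNA sensor IFI16 by 1.30 and MB21D1 upward and the kinase IKBKE downward by -0.98. MHC class I had 3 of 17 risen (6, and 2 fallen, adjusted over the list alone; 0.508), the peptide transporter TAP2 by 1.34, HLA-E by 1.06 and B2M by 0.38. The mitotic list had 3 of 20 risen and 5 fallen, or 7 and 5 adjusted over the list alone (0.877): AURKA rose by 0.82, and KIF11, BUB1 and TOP2A fell by 0.91, 0.84 and 0.66. T cell markers were near the floor, with 0 of 8 measured members past the threshold in either adjustment (0.676).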

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

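The tests of label exchange, karyotype, tissue RNA by covariates and tumour cell share were chosen after the result was seen, as were the way the Setd2 and T cell test was read and the expression limit of the gene length test, and the remaining tests of this part before. Of 492 groups of values tested for a library far from the rest of its group, 50 had one. Chance gives about 1 in 20 groups, and values of 1 library are not independent of each other. WT untreated replicate 1 and SETD2 KD VE822 replicate 4 account for 19 each.

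WT untreated replicate 1 was far above the other 6 libraries of its group in interferon-gamma, T cell and cytotoxic transcripts. Its list means were 8.79 for interferon-gamma and chemokines (others 7.50 to 7.84), 5.17 for T cells (4.65 to 4.77) and 4.12 for cytotoxic and NK cells (3.63 to 3.81). Single genes were Cxcl9 at 8.97 (6.32 to 6.65), Gbp4 at 8.36, Ciita at 8.41, Zbp1 at 10.26, Cgas at 6.28, Pdcd1 at 5.83, Nkg7 at 4.78, Xcr1 at 4.66 and Clec9a at 3.56. Dhcr7 was high at 10.62, and Stard4 at 11.45, Avil at 11.68 and Ptprr at 6.69 were low. Its chromosome medians were -0.15 for chromosome 6, 0.16 for chromosome 8 and -0.00748 for chromosome 15.

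SETD2 KD VE822 replicate 4 lacked most of the large rises of its group. Igf2 was at 6.37 (the other 4 libraries 10.82 to 11.35), Aoc1 at 5.41 (9.21 to 9.54), Cyp4f40 at 5.61, Kif1a at 7.44, Tpsab1 at 5.05, Ptgds at 7.14, Myom2 at 5.61, Lct at 5.94, Cd28 at 5.44, Ccr7 at 8.33, Rnaseh2c at 8.62 and Chrdl2 at 8.67, all low. Kcnk5 at 10.38 (7.55 to 8.17), Cdk1 at 11.62, Cd22 at 7.89, Pkhd1 at 9.70 and the dendritic cell list at 6.82 (6.32 to 6.37) were high. Its chromosome medians were -0.20 for chromosome 6 (0.03 to 0.11) and 0.14 for chromosome 10 (-0.14 to -0.10).

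The other 12 values came from 10 libraries. The skeletal muscle list was at 6.5 in WT untreated replicate 4 (4.38 to 5.07 in the others), the adipocyte list at 6.18 and Tpsab1 at 5.30 in SETD2 KD untreated replicate 6, the mesenchymal list at 11.13 in WT VE822 replicate 4, and the chromosome 15 median at 0.0350 in WT VE822 replicate 6. Igf2 was at 6.63 in SETD2 KD untreated replicate 3, Pou3f3 at 7.96 in WT VE822 replicate 5, Birc5 at 11.09 in WT untreated replicate 6, Mvd at 10.05 in SETD2 KD untreated replicate 2, and Prf1 at 3.52 and Zbp1 at 10.02 in SETD2 KD untreated replicate 5. Zbp1 was low at 9.59 in SETD2 KD VE822 replicate 5.

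Setd2 was lower, and 5530 and 3540 genes passed, between libraries labelled VE822 and untreated in WT and SETD2 KD labels. RNA of muscle, fat, fibroblasts or endothelium is argued against as the whole cause: with those 4 list means as covariates 4343 genes passed in WT labels and 3546 in SETD2 KD labels, and Setd2 still fell by 0.74 and by 1.05. Exchanged labels stay open, since 8 of 24 libraries are out of place by Setd2 as labelled and 0 after an exchange of the WT VE822 and SETD2 KD untreated labels, a test built on the same values that raised the question. Tumour cells of another karyotype may account for part of it, since the SD of 10 Mb bin medians was 0.0886 in WT labels (highest of 100 shuffles 0.0506) and 0.0635 in SETD2 KD labels (0.0417), but also 0.0222 (0.0169) between untreated genotype labels, and in SETD2 KD VE822 replicate 4 Setd2 was low at 9.96 without the chromosome 10 shift. An effect of VE822 itself also stays open and was not tested apart from these. Under exchanged labels, comparisons reported as VE822 against untreated would be between genotypes, and those between genotype labels would be between treatments. The interaction and the combined contrast would not change. The numbers in the sample titles are all higher in libraries labelled VE822 than in those labelled untreated. A difference that goes with that order cannot be told apart from the VE822 label.

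The T cell and interferon-gamma list means were higher in libraries labelled VE822, the latter past the threshold in SETD2 KD labels. A lower share of tumour cells that raises all other cell types alike is argued against by the macrophage list alone. The T cell minus macrophage difference of list means was 0.947 in WT labels (95% interval 0.63 to 1.26). In SETD2 KD labels it was 1.23 (0.89 to 1.57). Among the other lists of non-tumour cell types, only skeletal muscle was also lower, in SETD2 KD labels (4.75 to 4.47). Fibroblasts went from 10.05 to 10.76 in WT labels and from 9.75 to 10.26 in SETD2 KD labels, without passing. A lower share of tumour cells as part of the cause stays open. Whether T cell content follows the level of Setd2 cannot be told apart from no relation with 11 libraries: Pearson r was 0.0239 (permutation p 0.943) and Spearman rho -0.13 (permutation p 0.711), with r at 0.634 within WT VE822 (n = 6), -0.376 within SETD2 KD VE822 (n = 5) and 0.254 without the 2 libraries farthest from the median Setd2. An r of 0 or above had been laid down as evidence against, and that the bound must be passed by more than the spread was applied here only after r was seen. Recruitment of T cells under ATR inhibition stays open, as does whatever the labels stand for.

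In 786-O cells given the CHK1 inhibitor, the genes called higher had a shorter median span than those called lower, in a weak trend over all genes tested for it. Spearman rho of log2 fold change and genomic span was -0.27 over 10317 genes of those with a mean value of at least 5, and the median span was 15.6 kb for 1424 genes that rose and 50.9 kb for 1528 that fell. The span is that of the mouse gene of the same symbol, a stand-in found for 81.0% of the 12731 genes above that limit. Gene length may thus account for part of the changes, whether through slowed elongation, RNA quality or another length-dependent step, which these data do not separate. No test of a biological explanation was made.

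Other splits of the same libraries were fitted, 100 per comparison with the real one included. The real split called the most genes for VE822 in WT labels (5530 genes, highest other split 2117, 1 split as large). So it did for VE822 in SETD2 KD labels (3540, 1738, 1) and the combined contrast (3890, 2436, 1). With 100 splits, chance can be narrowed to about 1 in 100 at best. A count above those of random splits shows that the labelled sets differ, not why. Chance cannot be excluded for genotype labels under VE822 (2 genes, highest other 700, 21 splits as large). For genotype labels without treatment (0, highest other 1) and the interaction (0, highest other 2294) the count decides nothing, since with 0 genes all 100 splits are as large whatever the data. For the interaction, treatment labels were shuffled within each genotype label, so a split can carry the VE822 change itself into the interaction. What separates the libraries in the splits with 700 and 2294 genes was not tested.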

How the results depend on the processing

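The alternatives with covariates, chromosome medians removed, chromosomes 6, 8 and 10 left out, 5 doubted libraries left out, a mean human value of at least 5 and voom were chosen after the result was seen.

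In 786-O cells the 3878 genes became 6758 with a robust prior, 6074 with at least 50 counts in 2 libraries, 6226 with a mean of at least 5, 6416 and 6450 with voom under median-of-ratios and library size scaling, and 5582 with experiments as blocks. The 2 filters test fewer genes (11685 and 12731), and otherwise the cause was not tested. Leaving out 1 library gave 0 to 4658 genes: 0 without either untreated library, 3633 and 4658 without treated replicate 1 and 2. The group left with 1 library is then assumed to vary like the other. Of the 63 calls among genes the naming rule gives, 3 were lost with a robust prior: CXCL8 (limma adjusted p 0.0835), DNAH17 and CLDN2. The 7 lists became 4 with fry, 7 with blocks and 0 with an estimated correlation. The last has few degrees of freedom with 2 libraries per group. The planned count-based tests in other packages, a pseudocount of 0.1 and a mean value of at least 1 were not run, because the table holds log2 values with a floor of 2.47.

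In Renca, the count for VE822 in WT labels ran from 4334 to 5942 over 12 settings and from 4857 to 5672 over left-out libraries, in SETD2 KD labels from 2792 to 5189 and from 2835 to 4439, and for the combined contrast from 3039 to 5650 and from 3109 to 5119, all within 1.5 times the reported counts. The interaction stayed at 0 genes under every setting run. Between untreated genotype labels the 0 genes became 1 with trend=FALSE, 1 with quantile normalisation, 11 with library weights, 5 with covariates, 2 without the doubted libraries, 3 with only the groups compared, and 0 to 1 over left-out libraries (1 gene, and 1 list, without SETD2 KD untreated replicate 1). Under VE822 the 2 genes became 4 with no filter, 8 with centring, 1 with quantile normalisation, 5 with chromosome medians removed, 1 without chromosomes 6, 8 and 10, 0 with only the groups compared, and 2 to 46 over left-out libraries (46 without WT VE822 replicate 3, 24 without SETD2 KD VE822 replicate 1, 11 without WT VE822 replicate 1, 6 without WT VE822 replicate 5). The fit with only the groups compared takes the spread from those 2 groups, whereas the reported model shares 1 spread per gene over all 4. The cause of these changes was not tested.

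Tbk1 reversed with chromosome medians removed, to 0.0415 for VE822 in WT labels and 0.0216 for the combined contrast. It lies on chromosome 10, whose genes were lower as a whole. Of the named Renca genes, 6793 planned comparisons stayed on their side of the threshold, 59 crossed it upward and 79 downward. Those that stayed may include a change of sign where neither fit passed, here and in the counts that follow. Of the Renca comparisons added later, 1189 stayed, 21 crossed upward, 31 downward and 2 reversed. Of the named 786-O genes, 266 planned comparisons stayed, 14 crossed upward and 217 downward. Of the 786-O comparisons added later, 193 stayed and 10 crossed upward.

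Lists were called by camera with its preset correlation in 8 cases between untreated genotype labels, 11 under VE822 and 6 for the interaction, against 0 each by the test reported. With an estimated correlation camera called 0 lists for VE822 in WT labels, 0 in SETD2 KD labels and 0 for the combined contrast. For VE822 in WT labels 13 lists passed with chromosome medians removed, the cGAS-STING list among them (0.12, exact permutation test, adjusted p 0.0255), and 0 without the doubted libraries. There the smallest p possible with 6 against 3 libraries is 0.0119, and the differences of the T cell, MHC class II and cholesterol lists were 0.85, 0.72 and -0.51. Over left-out libraries the lists numbered 5 to 13 for VE822 in WT labels (5 without WT untreated replicate 2, 3, 5 or 6 or WT VE822 replicate 4, 13 without WT VE822 replicate 6), 7 to 11 in SETD2 KD labels, 8 to 13 for the combined contrast (13 without SETD2 KD VE822 replicate 4), 0 to 1 between untreated genotype labels, and 0 to 0 under VE822 and for the interaction. With the median over members, the p53 list passed for VE822 in WT labels (-0.13), in SETD2 KD labels (-0.17) and for the combined contrast (-0.10), and the interferon-gamma list passed in WT labels (1.07). So did the keratinocyte, ATR-CHK1 and stress response lists in WT labels (0.34, -0.10 and -0.20), the macrophage and endothelial lists in SETD2 KD labels (-0.22 and 0.63) and the macrophage, replication and histone lists for the combined contrast (-0.26, 0.07 and 0.55). The dendritic list in WT labels and the cholesterol and red blood cell lists in SETD2 KD labels lost their calls (0.45, -0.22 and 0.68; exact permutation test, adjusted p 0.162, 0.115 and 0.0675). Of list comparisons, 3384 planned kept their side, 52 crossed upward and 32 downward, and of those added later 385, 14 and 9. Depth limits the 786-O genes near the floor, and for Renca it is unknown.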

Other observations

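No test of this part was chosen after the result was seen, since only values are given. The first 2 principal components of the mouse libraries held 38.6% and 18.1% of the variance, and SETD2 KD VE822 replicate 4 stood at 2.19 and 46.1 on them. The correlation of the VE822 changes between genotype labels was 0.848 over genes with a mean rlog of at least 5.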
